A study of Homo sapiens with 6 samples.

How the data were processed

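Gene expression was measured in UMUC-14, an established human bladder cancer cell line, on Affymetrix U133 Plus 2.0 arrays, which carry short oligonucleotide probes for human transcripts. The 6 arrays formed 2 groups of 3. In the first group the cells received the lipofectamine transfection reagent without an siRNA. In the second group they were transfected with an siRNA against FGFR3, and each of the 3 arrays used a different siRNA: siFGFR3#35, siFGFR3#36 and siFGFR3#3. Per the labels' protocols, the cells were transfected for 40 h and 100 ng of total RNA was amplified and labelled with biotin. The labels name no non-targeting siRNA, so the presence of an siRNA and the knockdown of FGFR3 were compared together against the reagent alone. The labels also do not say whether the control arrays came from separate cultures, so the p-values measure the spread between these samples, which may in part be technical.

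The deposited values are log2 expression levels made by the authors with RMA in the affy package, per the submitters' processing notes, whose versions are not stated. RMA subtracts background, makes the distributions of all arrays equal and summarises the probes of each row, so a change that affected most genes in one direction would be reduced by it. The deposited table held 19361 rows, and 18669 of them were named by their listed Entrez gene ID with the suffix of a probe set. For these the probes had been regrouped with 1 row per gene, and no choice between several probe sets of a gene remained. The probe annotation used here gave 1 symbol for 18669 rows, and all of these were updated through a RefSeq gene table of GRCh38.p14. The other 692 rows were left unnamed, and 512 of them were among the rows tested. The rule fixed for excluding Affymetrix control probe sets was not applied as a separate step. Whether any unnamed row is such a control was not checked. Because the genome build behind the probe groups is not given in the sources used here, no coordinates are printed. The median of the arrays lay between 5.41 and 5.52, and no total count or depth exists for array data; the number of arrays limits the precision.

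Rows were ranked by their mean over the 6 arrays and the dimmest 30% were left out, which removed 5809 rows below a log2 level of 3.89 and kept 13552 rows, called genes below. The 2 groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of variance on mean level), and p-values were adjusted with the Benjamini-Hochberg method over the 13552 genes. A gene passed at an adjusted p under 0.05, two-sided. With 3 arrays against 3, an exact permutation test of a single gene cannot give a p below 0.1, so the model that shares information between genes was used. The siRNAs served as the replicates of the siFGFR3 group, so the error of each change holds the spread between siRNAs. The median SD of a gene was 0.0536 among controls and 0.129 among siFGFR3 arrays, and the model used a pooled value. For a gene that varied more between siRNAs than between controls, the pooled value was smaller than its spread between siRNAs. Errors are given as SD for group means and as SE for differences, with 3 arrays per group. The SE is that of the moderated statistic, in which the variance of a gene is drawn toward that of other genes. For genes that vary much between siRNAs, such as FGFR3 and RSAD2, it is smaller than their own arrays alone would give.

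Before the data were examined, 20 gene lists with 493 entries were written from general knowledge, of which 432 entries matched a row. Lists with at least 5 tested members, 18 of them, were compared with all other genes by limma's camera at a preset correlation between genes of 0.01, and adjusted over the 18 lists. The alternatives were camera with an estimated correlation and limma's fry, which asks whether the members of a list move on balance in one direction and makes no comparison with other genes. Each list also has a count of passing members, and a count adjusted over the list alone. The genes named in the text follow a rule that was fixed at the same time: FGFR3 and MYC, the 8 largest rises and the 8 largest falls among passing genes whose arrays separated the groups, and the 2 members of each list with the smallest adjusted p, or 4 for the list of FGFR and MAPK output. For each list of markers of other cell types the member with the highest level is named instead, whether or not it passes. Further members are named where 5 or fewer of a list rose or fell, and these were chosen after their values were seen.

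Each siRNA was also set against the 3 controls in a limma model with 4 levels, in which 1 array stands for each siRNA and is assumed to vary like the controls; its p-values compare arrays, not conditions. The changes of the siRNAs share the controls, so the correlation expected without any effect was taken from 100 simulations of unchanged arrays against the same controls. The overlap of called genes expected without any effect came from the same simulations, by taking as many top genes by moderated t in each direction as were called with each siRNA. The scripts were tested on simulated data made from the 13552 genes: for siFGFR3 against the reagent alone, the test recovered 47.8% of 67 genes changed by 0.5 on the log2 scale, 83.6% of 67 genes changed by 1 and 100% of 66 genes changed by 2, with 10 false calls. The list test called the 1 shifted list and no unshifted list. The single-siRNA model recovered 200 of 200 genes changed by 1 on the log2 scale with 1 siRNA. It called 0 genes with the siRNAs that had been given no change, and false calls with the changed siRNA were not counted. In all of these simulations genes were drawn independently, and in that of the single siRNAs the siRNA arrays had the spread of the controls. They do not show how often false calls arise where genes move together or siRNA arrays vary more. Far fewer genes were changed in the simulations than the 45.1% that passed in the real data. The shares recovered therefore do not carry over to the real comparison. In the real data the estimated correlation between members reached 0.905, for the interferon response list. Alternatives covered the filter, the scaling of the arrays, the moderation of variance, array weights, the model of the siRNAs, the list test and leaving out each array in turn. Alternatives that need several probe sets per gene were planned and could not apply to this table.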

Results

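The data comprise 6 arrays of UMUC-14 bladder cancer cells, 3 treated with lipofectamine reagent alone and 3 transfected with an siRNA against FGFR3, a receptor tyrosine kinase of the fibroblast growth factor family. Over the 13552 genes tested, the 3 reagent-alone arrays correlated with each other at r = 0.9978 to 0.9984. The siFGFR3 arrays, each with its own siRNA, correlated at 0.9848 to 0.991, and arrays of different groups at 0.9614 to 0.9772. The first principal component held 75.2% of the variance between arrays and the second 13%. These correlations are across genes, which are not independent replicates.

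The first comparison checks the target of the siRNAs. FGFR3 (Entrez gene 2261) was at 8.73 ± 0.03 (SD, n = 3) on the log2 scale in reagent-alone cells and at 7.69 ± 0.68 (SD, n = 3) in siFGFR3 cells. It fell by 1.04 (SE 0.30), or 2.06-fold, with an adjusted p of 0.0271 in limma, and all 3 siFGFR3 arrays lay below all 3 controls. The siFGFR3 arrays, 1 per siRNA, differed in its level. With siFGFR3#35 the FGFR3 signal was at 41.7% of the control level and with siFGFR3#36 at 33.3%, against 82.2% with siFGFR3#3, a 1.22-fold difference from the controls (adjusted p = 0.00079 in the 4-level limma model). On the log2 scale the siFGFR3#3 array lay 1.14 above the mean of the other siRNA arrays (adjusted p = 9.29e-07 in the same model). Without lipofectamine replicate 1, 2 or 3 the adjusted p was 0.0727, 0.078 or 0.0814, and without siFGFR3#35 it was 0.0705, while without siFGFR3#3 it was 0.00147.

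**Figure D1:**
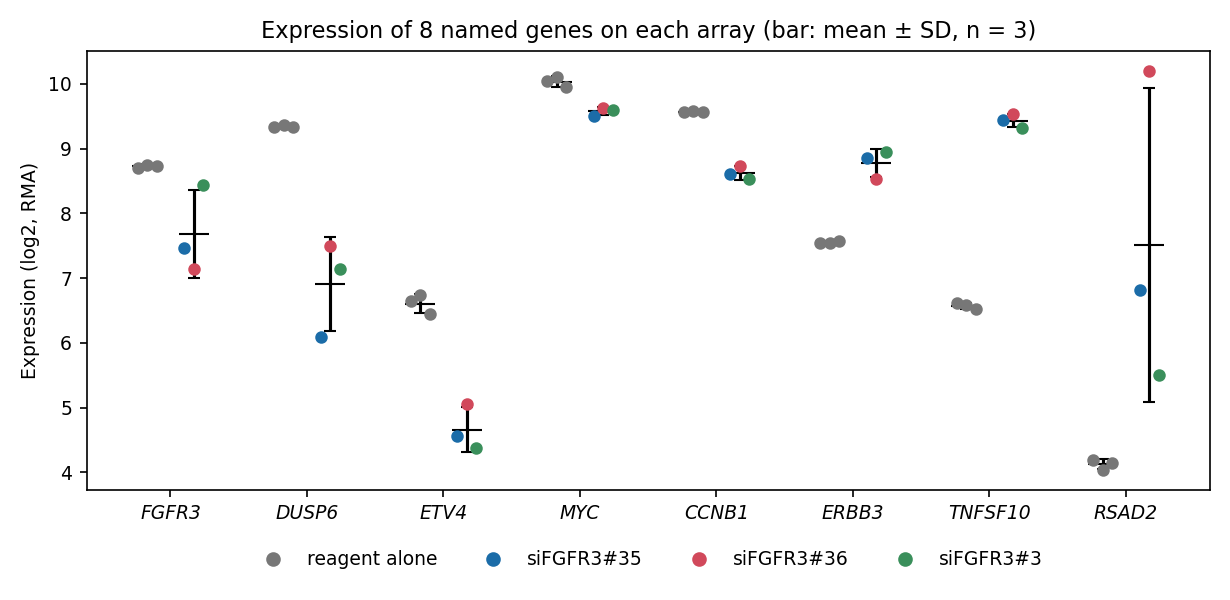
Expression of 8 named genes (log2, vertical axis) on each of the 6 arrays, with points coloured by reagent alone or siRNA and bars giving the mean ± SD of 3 arrays. FGFR3 falls least with siFGFR3#3, RSAD2 spreads most between the siRNAs, and TNFSF10 lies 2.86 above the controls on average with little spread.

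The second comparison asks which genes differed between siFGFR3 cells and cells given the reagent alone. The largest falls were in LOXL1, an enzyme that cross-links elastin, which fell by 3.46 (SE 0.37, adjusted p = 0.00094), and in the anion transporter SLCO4A1, which fell by 2.80 (SE 0.35, adjusted p = 0.0015). LOXL1-AS1, transcribed antisense to LOXL1, changed by −2.62, the pattern recognition protein PTX3 by −2.54, the AP-1 subunit FOSL1 by −2.51, the ERK phosphatase DUSP6 by −2.44, the transcription factor DMRT1 by −2.34 and the ETS factor ETV5 by −2.13, all with an adjusted p under 0.05. The mean of DMRT1 in siFGFR3 cells was 3.67, below the 3.89 at which dim rows were cut, and signal over background was not analysed here, so the size and rank of its change are uncertain. Among the largest rises, RSAD2, an antiviral enzyme induced by interferon, rose by 3.38 (SE 1.05, adjusted p = 0.0354), the ubiquitin-like protein UBD by 3.37 (SE 0.18, adjusted p = 0.0002) and the interferon-induced IFI44L by 3.33 (SE 0.97, adjusted p = 0.0286). With siFGFR3#35, siFGFR3#36 and siFGFR3#3, RSAD2 rose by 2.70, 6.08 and 1.38 and IFI44L by 2.91, 5.71 and 1.36. The size and rank of these 2 rises therefore lean on the siFGFR3#36 array. The scavenger receptor OLR1 rose by 3.23, the protease TMPRSS11E by 2.86, the death ligand TNFSF10 (TRAIL) by 2.86, the antiviral TRIM22 by 2.75 and the selenium carrier SELENOP by 2.70. The mean of SELENOP in reagent-alone cells, 3.89, lay at the cut for dim rows and 2 of the 3 controls below it (3.88 and 3.79), so the size and rank of its rise are uncertain as well. TNFSF10 had the smallest adjusted p of all genes tested, 1.87e-05 (SE 0.07). RSAD2 and IFI44L no longer passed without any 1 of the 3 controls (adjusted p = 0.068 to 0.097) or without siFGFR3#35 (0.0516 and 0.05), and SELENOP no longer passed without any 1 control or without siFGFR3#3 (0.0506 to 0.0596).

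In all, 2789 genes were higher and 3329 lower in siFGFR3 cells, 45.1% of the genes tested. Their median absolute change was 0.431 on the log2 scale. At least 2-fold changes were found for 328 higher and 120 lower genes, and at least 1.5-fold changes for 1029 and 721. In 60.8% of all tested genes the arrays of the groups did not overlap, where chance gives 10%. With each array centred on its median, 2312 genes were higher and 4285 lower, so that the share of higher genes among those changed was 35% in place of 45.6%. Fewer genes passed without lipofectamine replicate 1, 2 or 3: 1713, 1769 and 1672 higher and 1985, 1990 and 1987 lower.

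Of 28 tested genes known to respond to FGFR and MAPK signalling, 21 fell, 3 rose and 4 did not pass; adjusted over the list alone, 22 fell and 3 rose. The ETS factor ETV4 fell by 1.95 (SE 0.18), the feedback inhibitor SPRY4 fell by 1.41 (SE 0.14) and the uridine phosphorylase UPP1 fell by 0.60 (SE 0.07), beside DUSP6, ETV5 and FOSL1 above. The ephrin receptor EPHA4 rose by 1.75 (SE 0.10, adjusted p = 0.0002), and the other members that rose, chosen after their values were seen, were EGR1 by 0.82 and TFAP2C by 0.35. The list's median change was −0.82 (camera adjusted p = 4.89e-05; adjusted p = 0.485 with an estimated correlation).

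All 31 tested MYC targets fell, also when adjusted over the list alone, with a median of −0.77. Among them were ODC1, the first enzyme of polyamine synthesis, which fell by 1.36 (SE 0.12), and the nucleolar protein NCL, which fell by 0.55 (SE 0.05). MYC itself fell by 0.46 (SE 0.06, adjusted p = 0.002), from 10.04 ± 0.08 to 9.58 ± 0.06 (SD, n = 3). The camera adjusted p of the list was 4.33e-12 and became an adjusted p of 0.485 with an estimated correlation.

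Of 30 genes of S phase and replication, 24 fell, 0 rose and 6 did not pass (25 fell when adjusted over the list alone), including the thymidylate synthase TYMS, which fell by 0.76 (SE 0.09), and the replication factor subunit RFC4, which fell by 0.57 (SE 0.08). The median was −0.47 (camera adjusted p = 6.93e-07; adjusted p = 0.485 with an estimated correlation). By siRNA the median was −0.45 with siFGFR3#35, −0.31 with siFGFR3#36 and −0.67 with siFGFR3#3. Without lipofectamine replicate 2 or 3, 15 of these genes fell. Of 30 genes of G2 and mitosis, 26 fell, 0 rose and 4 did not pass (27 fell when adjusted over the list alone). The mitotic cyclin CCNB1 fell by 0.95 (SE 0.07) and CDC20, an activator of the anaphase-promoting complex, fell by 0.93 (SE 0.07). The median was −0.52 (camera adjusted p = 8.64e-09; adjusted p = 0.485 with an estimated correlation). Cell cycle inhibitors and p53 targets went both ways, with 7 of 18 higher, 4 lower and 7 not passing, and the same counts adjusted over the list alone (camera adjusted p = 0.138). Within that list the stress-induced TP53INP1 rose by 2.43 (SE 0.29) and the kinase PLK3 fell by 0.85 (SE 0.10), beside GDF15, FAS and MDM2 (−0.97, −0.38 and −0.43). Without any 1 of the controls, 2 in place of 4 members were lower.

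In cholesterol and fatty acid synthesis, 11 of 22 genes fell, 0 rose and 11 did not pass (12 fell when adjusted over the list alone), with FDPS of the mevalonate pathway at −0.56 (SE 0.09) and the fatty acid elongase ELOVL6 at −0.32 (SE 0.07). The median was −0.31 (camera adjusted p = 0.0237; adjusted p = 0.521 with an estimated correlation). The members that fell numbered 6, 6 and 7 without lipofectamine replicate 1, 2 or 3, and ELOVL6 did not pass without lipofectamine replicate 1 (adjusted p = 0.0511). In glycolysis and the hypoxia response, 13 of 22 genes fell, 3 rose and 6 did not pass (15 fell and 3 rose when adjusted over the list alone). The glycolytic enzyme ENO1 fell by 0.53 (SE 0.06), while the hypoxia-induced peptide ADM rose by 1.13 (SE 0.13), and PFKFB3 and PFKL rose by 0.28 and 0.24. The median was −0.40 (camera adjusted p = 0.0151; adjusted p = 0.521 with an estimated correlation), and without any 1 of the controls 1 member rose in place of 3. Of 24 genes of ATF4 and the unfolded protein response, 10 fell, 4 rose and 10 did not pass (12 fell and 4 rose when adjusted over the list alone; camera adjusted p = 0.0834). The serine and glycine enzyme SHMT2 fell by 0.68 (SE 0.07) and the pseudokinase TRIB3 fell by 0.93 (SE 0.10), and the members that rose were SESN2, DNAJB9, HERPUD1 and DDIT4 (0.38 to 0.64). Of 18 cytosolic ribosomal proteins, 6 fell, 0 rose and 12 did not pass, and adjusted over the list alone the counts were the same (camera adjusted p = 0.0859); RPL8 fell by 0.26 (SE 0.04) and RPL5 fell by 0.24 (SE 0.05). With arrays centred on their median, 10 ribosomal proteins fell (camera adjusted p = 0.0113), and without lipofectamine replicate 1, 2 or 3, 3, 3 and 2 fell.

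Of 28 tested interferon response genes, 12 rose, 0 fell and 16 did not pass (13 rose when adjusted over the list alone). The transcription factor IRF1 rose by 1.12 (SE 0.09, adjusted p = 0.00045) and the antiviral GTPase MX2 by 2.48 (SE 0.39, adjusted p = 0.0032). The median change of the list was 1.38 (camera adjusted p = 1.13e-05; adjusted p = 0.521 with an estimated correlation; adjusted p = 0.0783 in fry). By siRNA the median was 0.96 with siFGFR3#35, 2.73 with siFGFR3#36 and 0.47 with siFGFR3#3, and 27 of the 28 members were higher with siFGFR3#36 than the mean of the other siRNAs (adjusted p under 0.05 in the 4-level limma model), which compares single arrays. Without lipofectamine replicate 1, 2 or 3 the members that rose numbered 3, 4 and 3, without siFGFR3#35 5, without siFGFR3#36 19 and without siFGFR3#3 20. Of 17 genes of NF-kB and inflammatory cytokines, 4 rose, 2 fell and 11 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.149). The NF-kB inhibitor NFKBIA rose by 0.76 (SE 0.14) and the cytokine IL1A fell by 1.13 (SE 0.19). The others that rose were TNFAIP2, RELB and NFKB2 (0.57 to 0.73), and LTB fell by 0.27. Without siFGFR3#35, 10 of the 17 rose and the list passed (camera adjusted p = 0.0179), as it did in the 4-level model (0.0279), and without any 1 of the controls 1 member fell.

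Urothelial luminal differentiation genes rose in 14 of 24 cases, fell in 2 and did not pass in 8, with the same counts adjusted over the list alone. The secreted phospholipase PLA2G2A rose by 1.69 (SE 0.08) and the uroplakin UPK3B by 1.03 (SE 0.06). The members that fell, chosen after their values were seen, were the fatty acid-binding protein FABP4 (−1.77) and the reductase DHRS2 (−0.25), and 1 member fell without any 1 of the controls. The list's median was 0.23 (camera adjusted p = 0.00057; adjusted p = 0.474 with an estimated correlation). Of 14 basal and squamous genes, 4 rose, 4 fell and 6 did not pass (4 rose and 6 fell when adjusted over the list alone; camera adjusted p = 0.666). The hyaluronan receptor CD44 fell by 1.13 (SE 0.06) and the basal keratin KRT5 fell by 0.98 (SE 0.10), beside KRT14 and TGM1 (−0.50 and −0.35), whose means in siFGFR3 cells, 3.70 and 3.78, lay below the cut for dim rows of 3.89. ITGB4, CDH3, S100A9 and IVL rose (0.36 to 0.52). Of this list 0, 2 and 0 members rose and 2, 3 and 2 fell without lipofectamine replicate 1, 2 or 3, and 2 rose without siFGFR3#3. Of 18 mesenchymal and invasion genes, 7 rose, 4 fell and 7 did not pass, with the same counts adjusted over the list alone. The collagen cross-linking enzyme LOX rose by 1.42 (SE 0.13) and the actin-binding protein TAGLN by 1.13 (SE 0.19), and MMP9, SNAI1, VIM and PLAT fell (−0.84 to −0.25). The mean of LOX in reagent-alone cells was 3.58 and that of VIM in siFGFR3 cells 3.78, both below the same cut, so the sizes of their changes are uncertain. This list's median was 0.31 and its camera adjusted p of 0.0499 was lost with an estimated correlation (adjusted p = 0.485), without the filter on dim genes (0.159), without the variance trend (0.0556) and without lipofectamine replicate 1 (0.0652). The members that fell numbered 2, 0 and 0 without lipofectamine replicate 1, 2 or 3, and 1 without siFGFR3#3.

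Receptor genes changed individually. Of 7 tested members of the list of ERBB receptors and ligands, 4 rose, 2 fell and 1 did not pass, also when adjusted over the list alone (camera adjusted p = 0.23). The receptor ERBB3 rose by 1.23 (SE 0.11, adjusted p = 0.00059) and the ligand NRG4 by 0.68 (SE 0.09). ERBB2 and BTC also rose (0.73 and 0.66). The ligand TGFA fell (−0.75), as did ERRFI1 (−0.56), a list member that is neither a receptor nor a ligand. Of 7 tested members of the list of FGF receptors and ligands, which leaves out FGFR3, 1 rose, 2 fell and 4 did not pass. The counts were the same adjusted over the list alone (camera adjusted p = 0.738). No FGF ligand was among these members, which were FGFBP1, FGFR1, FGFR2, FGFR4, FGFRL1, FRS3 and KLB. The receptor FGFR2 rose by 1.39 (SE 0.28) and the FGF-binding protein FGFBP1 fell by 1.85 (SE 0.26). The other member that fell, chosen after its values were seen, was FGFR1, at −0.26 (adjusted p = 0.03). Without lipofectamine replicate 1 or 2, siFGFR3#35 or siFGFR3#3, 1 member fell. Of 19 apoptosis regulators, 6 rose, 1 fell and 12 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.0793, 0.0304 without siFGFR3#35 and 0.0438 without the filter on dim genes; adjusted p = 0.0033 in fry). Beside TNFSF10, the mitochondrial protein BNIP3L rose by 0.77 (SE 0.06). The member that fell, chosen after its values were seen, was the TRAIL receptor TNFRSF10A, at −1.19 (adjusted p = 0.0024), and without siFGFR3#36 4 members fell.

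Markers of other cell types that a culture could hold were also listed. Of 9 leukocyte markers, 2 rose, 2 fell and 5 did not pass (2 rose and 3 fell when adjusted over the list alone; camera adjusted p = 0.569; adjusted p = 0.0481 toward lower expression in fry). The median of this list was −0.21 and its mean 0.03, so the median and camera's direction differed in sign from the mean. The members that rose were HLA-DRA by 1.61 and CD74 by 0.53, both MHC class II genes, and those that fell were CORO1A (−0.36) and CD3D (−0.47), all named after their values were seen. Of the leukocyte markers 1 rose without lipofectamine replicate 1 or 2. LCP1, the marker of this list with the highest level, was at 9.15 in controls and changed by −0.30 (adjusted p = 0.0581). Of 4 fibroblast markers 2 rose, 1 fell and 1 did not pass; COL1A1 rose by 0.64 (SE 0.11, adjusted p = 0.0039), from 5.42 to 6.06. The others that changed, chosen after their values were seen, were COL5A1, which rose by 0.47, and THY1, which fell by 0.34. None of 3 endothelial markers passed in limma (0 at an adjusted p under 0.05), and ESAM changed by 0.14 (adjusted p = 0.292). These last lists held too few tested genes for camera.

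Of the 18 lists tested with camera, 9 passed, 3 toward higher and 6 toward lower expression. With an estimated correlation 0 of the 18 passed, and the smallest adjusted p was 0.474. In fry 16 of the 18 passed. Fry makes no comparison with other genes, and 45.1% of all genes tested passed in limma. A pass in fry therefore does not set a list apart from other genes. Beside the apoptosis regulators and leukocyte markers, the lists that passed there and not with camera were ERBB receptors and ligands and cell cycle inhibitors and p53 targets toward higher expression (adjusted p = 0.00484 and 0.0108), and ATF4 and unfolded protein response, basal and squamous genes, FGF receptors and ligands and cytosolic ribosomal proteins toward lower expression (0.00584, 0.00663, 0.0313 and 0.0334).

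**Figure D2:**
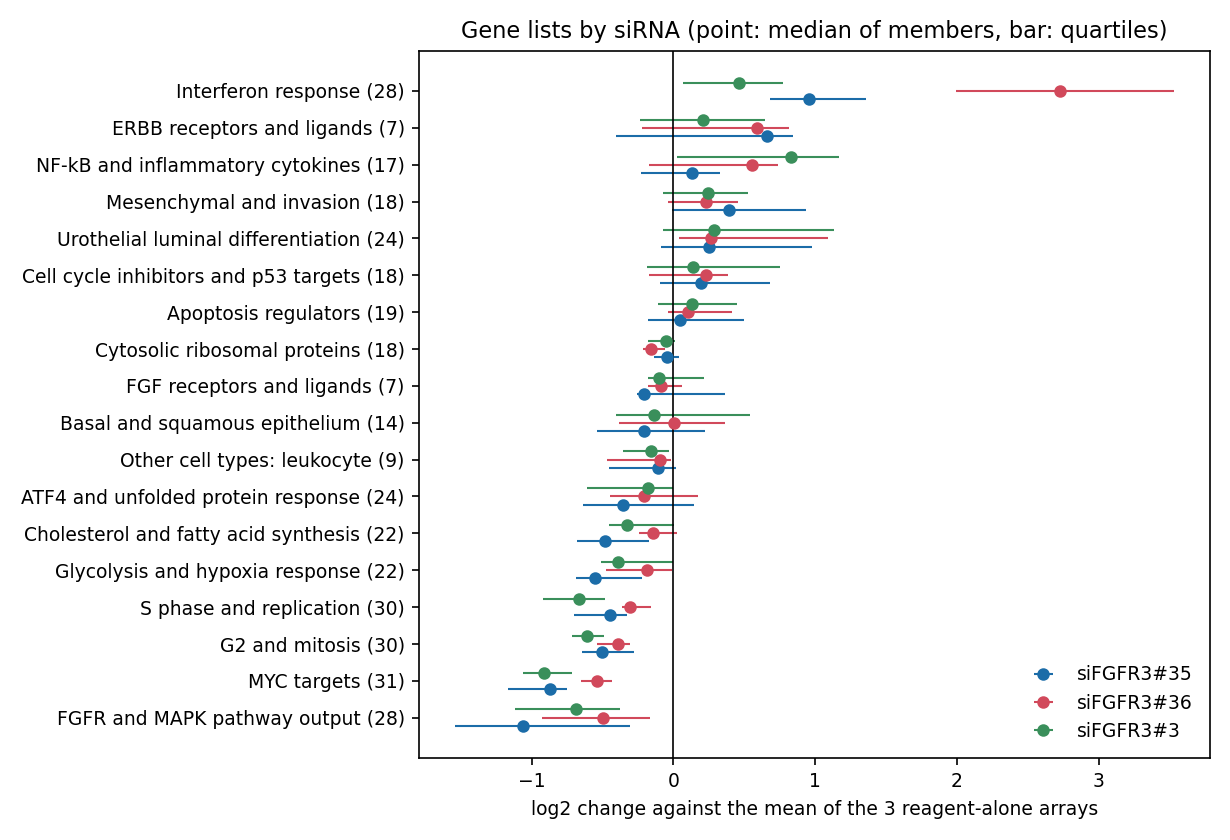
Median log2 change of the members of each gene list (horizontal axis) for each siRNA array against the mean of the 3 reagent-alone arrays, with bars from the lower to the upper quartile of members and the number of tested members in parentheses. MYC targets and FGFR and MAPK output lie below 0 with every siRNA, and the interferon response lies highest with siFGFR3#36, at a median of 2.73.

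The third comparison sets the siRNAs against each other. Across the 13552 genes, the log2 changes with siFGFR3#35 and siFGFR3#3 correlated at r = 0.868 (rho = 0.852), those with siFGFR3#35 and siFGFR3#36 at 0.762 (rho = 0.773) and those with siFGFR3#36 and siFGFR3#3 at 0.761 (rho = 0.801). Unchanged arrays simulated against the same controls gave r = 0.249. The covariances were 0.219, 0.166 and 0.153 in the same order, against 0.00193 in the simulation. Genes are not independent replicates, and 3 controls cannot be split into parts of at least 2 arrays each, so part of the excess may come from the shared controls.

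MYC targets had median changes of −0.87 with siFGFR3#35, −0.54 with siFGFR3#36 and −0.92 with siFGFR3#3, and FGFR and MAPK output had −1.06, −0.49 and −0.69. DUSP6 changed by −3.26, −1.86 and −2.20 with siFGFR3#35, siFGFR3#36 and siFGFR3#3, ETV4 by −2.05, −1.56 and −2.24 and CCNB1 by −0.96, −0.84 and −1.05. TNFSF10 rose by 2.87, 2.96 and 2.75 in the same order. RSAD2 rose by 2.70, 6.08 and 1.38. In the 4-level limma model 4123 genes were higher and 4100 lower with siFGFR3#35 alone, with siFGFR3#36 3080 and 3630, and with siFGFR3#3 4056 and 4107. Of these, 2285 genes were higher and 2401 lower with every siRNA, where unchanged arrays simulated against the same controls, with lists of these sizes, shared 661 and 751 on average and independent lists would share 280 and 333. The simulated values leave out real effects and the independent ones the shared controls, and part of the excess over either may come from the shared controls. By pairs, 2498 genes were higher with both siFGFR3#35 and siFGFR3#36 (1319 simulated, 937 for independent lists), 3243 with siFGFR3#35 and siFGFR3#3 (1663 and 1234) and 2570 with siFGFR3#36 and siFGFR3#3 (1304 and 922). The genes lower in both numbered 2705, 3087 and 2740 in the same order (1512, 1678 and 1511 simulated; 1098, 1243 and 1100 for independent lists). A further 2814 genes passed with 1 siRNA only, 414 passed in opposite directions with different siRNAs and 3027 passed with none. These calls rest on 1 array per siRNA.

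**Figure D3:**
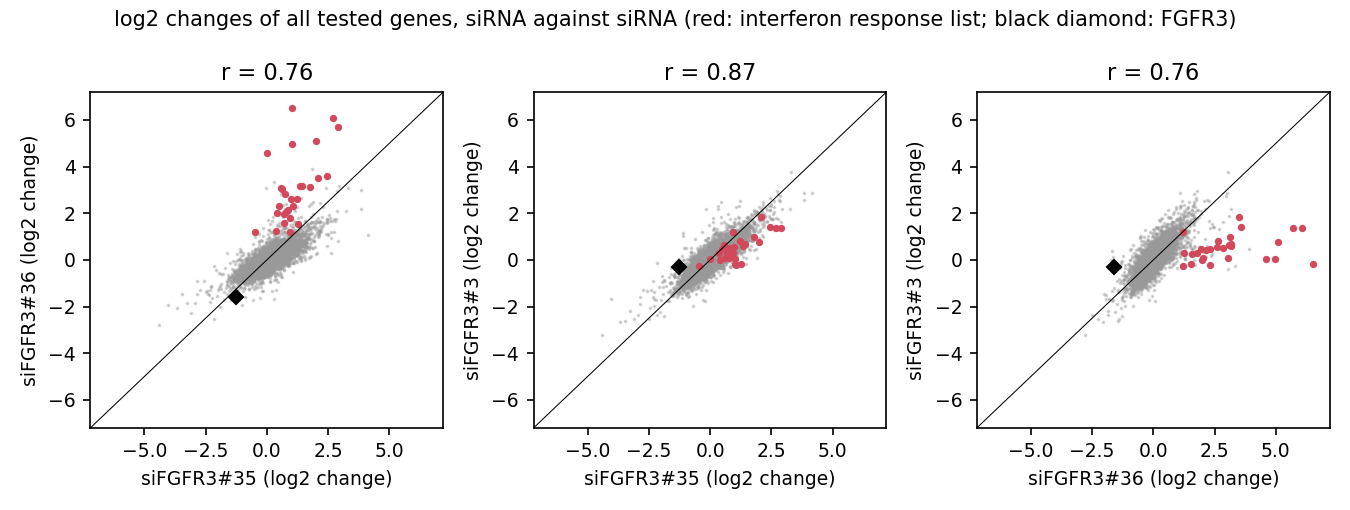
Log2 change against reagent alone of each tested gene for each pair of siRNAs, with the line of equality. In the panels with siFGFR3#36, interferon response genes, in red, lie mostly on its side of the line, and FGFR3, the black diamond, changes by −0.28 with siFGFR3#3 against −1.26 and −1.59 with the other siRNAs.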

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

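All tests of explanations in this part were chosen after the results were seen. The differences between siRNAs come from the 4-level limma model, with 1 array per siRNA, and so compare arrays.

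The interferon response list differed between the siFGFR3 arrays: 27 of its 28 members were higher with siFGFR3#36 than the mean of the other siRNAs, 27 were lower with siFGFR3#3 and 23 lower with siFGFR3#35. A first candidate explanation is a response to lost FGFR3 output in proportion to its fall. The median of the FGFR and MAPK list was −0.49 with siFGFR3#36, −1.06 with siFGFR3#35 and −0.69 with siFGFR3#3. The interferon medians were 2.73, 0.96 and 0.47 in the same order, so the array with the smallest fall in output had the largest rise. Over interferon members, the median difference of siFGFR3#36 minus siFGFR3#35 was 1.61. But that difference is the pattern itself and 1 array per siRNA gives no spread between arrays, so a response in proportion to lost output stays open. The order of the arrays by interferon median matched their order by FGFR3 level, but that is 1 of 6 possible orders, so the FGFR3 RNA level itself cannot be decided either. Sensing of the transfected siRNA also stays open: the lowest of the 3 list medians was 0.466, against at most 0.024 in size for a control array, and controls without an siRNA cannot separate this from loss of FGFR3. In single-siRNA calls 26, 28 and 19 members were higher with siFGFR3#35, siFGFR3#36 and siFGFR3#3, and 1, 0 and 3 were lower.

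FGFR3 itself differed between these arrays, lying 1.14 higher on the log2 scale with siFGFR3#3 than the mean of the other siRNAs. If this array were a control without siRNA, its MYC targets should lie near the controls, but their median change was −0.915, where the control arrays spanned −0.0266 to 0.0246. Weaker delivery with responses in proportion to FGFR3 would shrink all changes as it did that of FGFR3, to a ratio of 0.199; the slope of all genes on the mean of the other siRNAs was 0.953, but both sides share the controls and unchanged arrays would give 0.4. With the covariance and variance of unchanged arrays taken off (0.00193 of 0.186 and 0.00484 of 0.195, from the spread of the controls) the slope was 0.967 (95% bootstrap bounds over genes 0.941 to 0.993), which argues against it for this array, though not against responses that are already full at a small fall. The bounds treat genes as independent and hold no spread between arrays, so they do not cover a repeat of this transfection. FGFR and MAPK output was lower with siFGFR3#3 (median −0.69), so loss of FGFR3 protein with its RNA left, or probes that still detect the remaining RNA, cannot be told apart here, since neither protein nor probe positions were analysed. A response to any transfected siRNA was not tested and also stays open.

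Other lists differed between the arrays as well. With siFGFR3#36, 28 of 31 MYC targets and 28 of 30 genes of S phase and replication were higher than the mean of the other siRNAs (median differences 0.352 and 0.313), and with siFGFR3#3 25 of the 30 genes of S phase were lower (−0.291). Of 17 genes of NF-kB and inflammatory cytokines, 14 were lower and 1 higher with siFGFR3#35 than the mean of the other siRNAs (median difference −0.53), and 12 were higher and 1 lower with siFGFR3#3 (0.529), with list medians of 0.13 with siFGFR3#35, 0.55 with siFGFR3#36 and 0.83 with siFGFR3#3.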

How the results depend on the processing

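The counts of list members under each setting and the test of splits were chosen after seeing the data; the other alternatives were planned. Estimated correlation in camera left 0 lists passing and fry gave 16, where the other planned settings gave 8 to 12. The 4-level model with the spread of the controls raised the genes higher in siFGFR3 to 4407. Leaving out each array in turn gave 1672 to 3591 genes higher, 1985 to 3672 genes lower and an FGFR3 level change of −1.424 to −0.7721. Leaving out any 1 of the controls had a similar effect. Without lipofectamine replicate 1, 2 or 3, 1713, 1769 and 1672 genes were higher and 1985, 1990 and 1987 lower. Of these, 3665, 3727 and 3636 were among the 6118 changed genes in the same direction. FGFR3 missed the threshold without each of these controls (adjusted p = 0.0727, 0.078 and 0.0814 in limma), as it did without siFGFR3#35 (0.0705). Such fits hold fewer arrays. FGFR3 passed in the other planned settings. Of 436 comparisons of named genes other than FGFR3 under planned settings, 434 kept their side of the threshold and 2 newly passed, both for LCP1; of 330 such comparisons with an array left out, 316 kept it, 13 were lost (RSAD2, IFI44L, SELENOP and ELOVL6) and 1, LCP1, newly passed. Of 178 comparisons of lists under planned settings 151 kept theirs, 12 were lost and 15 newly passed, and of 108 with an array left out 103, 1 and 4; 0 reversed. ATF4 and unfolded protein response newly passed with the 50% dimmest genes left out (0.0487), with array weights (0.0446), in the 4-level model (0.0451) and without siFGFR3#36 (0.0429), and cytosolic ribosomal proteins without siFGFR3#35 (0.0304) or with the 50% dimmest genes left out (0.0487). The cause of these changes was not tested. The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 2789 higher and 3329 lower genes and the highest other 0 in limma, with 230 at an unadjusted p under 0.05 against 7387; 1 of the 10 splits reached each real count. For lists passing with camera at the preset correlation, the real value was 9, the highest other was also 9, and 2 of the 10 splits gave as many. Every other split put arrays of both groups in each part, so it kept part of the real difference in its contrast and its spread. The counts of these splits are therefore not the level expected without any effect. No paired analysis was run. The title of the siFGFR3#35 array ends in a 2 and those of siFGFR3#36 and siFGFR3#3 in a 1. The labels do not say what these marks mean, so they were not used to pair arrays with the controls. Any difference that they mark cannot be told apart from the siRNA, since each siRNA has 1 array. Averaging probe sets, testing each probe set and testing other FGFR3 probe sets were not run, because the table holds 1 row per gene. Signal over background was not analysed here; the filter on dim rows stands in for it.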

Other observations

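All lists and tests in this part were chosen after values of some of their members were seen, and their adjusted p-values cover the 6 lists added at that stage. Genes of MHC class I presentation, which load peptides for display to T cells, rose in 14 of 16 cases, fell in 0 and did not pass in 2, with the loading protein TAPBP higher by 0.91 (SE 0.06), the immunoproteasome subunit PSMB10 by 0.87 (SE 0.08) and HLA-B by 0.77 (SE 0.08). The median was 0.61 (camera adjusted p = 3.62e-07; adjusted p = 0.138 with an estimated correlation), at 0.56, 0.79 and 0.48 with siFGFR3#35, siFGFR3#36 and siFGFR3#3. Lysosomal genes rose in 17 of 22 cases, fell in 1 and did not pass in 4, with the protease CTSS higher by 1.54 (SE 0.09), the acid glucosidase GAA by 1.00 (SE 0.06) and the galactosidase GLA lower, at −0.75 (SE 0.07). Their median was 0.46 (camera adjusted p = 1.16e-06; adjusted p = 0.12 with an estimated correlation).

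Of 19 cytosolic tRNA synthetases, 15 fell, 1 rose and 3 did not pass, with YARS1 at −0.98 (SE 0.08) and QARS1 at 0.39 (SE 0.10). The median was −0.42 (camera adjusted p = 8.7e-06; adjusted p = 0.106 with an estimated correlation). Of 19 genes of RNA polymerases I and III, which transcribe ribosomal and transfer RNA, 16 fell, 0 rose and 3 did not pass, with POLR1E at −0.92 (SE 0.09) and POLR3G at −0.89 (SE 0.11); the mean of POLR3G in siFGFR3 cells was 3.74, below the 3.89 at which dim rows were cut. Their median was −0.47 (camera adjusted p = 2.33e-06; adjusted p = 0.12 with an estimated correlation), and POLR1B is also a member of the MYC target list. Of 22 subunits of respiratory chain complex I 5 fell (NDUFB9, NDUFB10, NDUFS3, NDUFS4 and NDUFB6), 3 rose (NDUFA2, NDUFA3 and NDUFB1) and 14 did not pass, with a median of −0.07 (camera adjusted p = 0.399). This list still passed toward lower expression in fry (adjusted p = 0.00199).

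Targets of FOXO transcription factors, which AKT holds out of the nucleus, rose in 14 of 20 cases, fell in 0 and did not pass in 6. The median was 0.69 (camera adjusted p = 2.05e-06, and 0.106 with an estimated correlation). By siRNA it was 0.716 with siFGFR3#35, 0.521 with siFGFR3#36 and 0.718 with siFGFR3#3. The smallest rise was thus on the array with the lowest FGFR3, at 33.3% of control, and the largest on that with 82.2%. With 1 array per siRNA, this cannot decide whether the rise depends on the FGFR3 level. A hypothesis is that loss of FGFR3 may lower the restraint of AKT on FOXO. Its test used the 14 members whose values had not been seen when the list was written: 9 of them rose, their median was 0.66 and their camera p was 0.000148 (p = 0.03 with an estimated correlation). Among these 14, PIK3IP1 was higher by 1.66 (SE 0.20), CCNG2 by 1.42 (SE 0.20) and GABARAPL1 by 1.22 (SE 0.19), while IRS2 changed by 0.01 (SE 0.07) and SOD2 by −0.07 (SE 0.10), neither passing. The test shows that further listed targets rose against other genes on the same arrays. It does not show FOXO activity, and because no non-targeting siRNA was analysed here, a response to siRNA in general stays open.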
